A study of Homo sapiens with 5 samples.

How the data were processed

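FOXO3A occupancy was measured by CUT&Tag, in which an antibody directs a Tn5 transposase to the chromatin around its target so that nearby DNA is cut and tagged for sequencing. The 5 libraries came from 2 human leukemia cell lines, 3 from THP-1 and 2 from U-937, and all used the same FOXO3A antibody per the labels. No control library (IgG or input) was used here. Per the submitters' processing notes, Bowtie2 and Picard were used and the genome build was hg38, with no versions or roles stated. The peak caller, its settings, its background and the number of reads are not given in the sources used here, so the depth behind each peak is unknown.

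The authors deposited a peak list per library, not a list of pooled libraries. Only replicate 1 of each line held peaks, and the other 3 libraries held a statement that no peaks were found. For each peak the authors deposited a start, an end, a summit, an integer score, a fold enrichment (a linear ratio over a background that is not stated), and -log10 of a p-value and of a q-value, as read from the narrowPeak layout because the lists have no header. The deposited score was 10 times the -log10 q, rounded down, in 1281 of the 1282 THP-1 peaks, and 10 times the -log10 p in all 2272 U-937 peaks. The lowest -log10 p was 4.80 in the THP-1 list and 5.02 in the U-937 list. The THP-1 list included contigs outside the chromosomes and the U-937 list did not, so both lists had been made or filtered differently. Fold enrichment was used only within its own list.

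Peaks on chromosomes 1 to 22, X and Y were analysed, and coordinates are given in hg38, counted from 1. A line's peak set was to be the peaks present in at least 2 libraries where at least 2 libraries held 100 or more peaks. As each line had 1 such library, its list was the line's set, without a replicate check. Each test compared 2 peak lists, not replicated conditions, and peaks are not independent replicates.

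No genome sequence was used here. The 18 planned motifs, the forkhead motif among them, were therefore not tested, backgrounds were not matched on GC content and random placements did not avoid assembly gaps. The gene table (RefSeq annotation of the same assembly) gave gene spans without strand or exons. The planned promoter class, within 1000 bp of a transcription start, became within 1000 bp of either end of a gene (a gene boundary), and the planned exon and intron classes became other gene body. A gene boundary is thus a start or an end. Of 59792 genes in the table, 831 whose coordinates broke the ascending order of their chromosome were left out as belonging to other scaffolds. The remaining 58961 included 19866 protein-coding and 18010 lncRNA genes, and boundaries of both these kinds were used for location.

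Location was taken at the summit and compared with 1000 random placements, each drawing a new summit position along the peak's chromosome. Width was kept where whole peaks were placed, as for mitochondrial pseudogenes and shared peaks. These placements are called a permutation of positions below, although positions were drawn anew and not exchanged. Their p-values were one-sided in the observed direction, and the smallest they can give is 0.001. Shared peaks overlapped by at least 1 bp and were compared with 1000 random placements of the U-937 peaks. Shares have exact (Clopper-Pearson) 95% intervals that cover counting error only. Differences between lists, gene lists and target genes were tested with two-sided Fisher's exact tests. Medians of fold enrichment were compared with a two-sided permutation test of 100000 resamples, whose smallest possible p is 1e-05. Benjamini-Hochberg adjustment covered 38 tests of 19 gene lists in both lines, 19 tests between lines, 7 tests of location between lines and 10 tests of small RNA genes. All 659 symbols of the gene lists were found in the table.

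The gene lists and the rule for named genes were fixed before the data were examined. The rule named the 10 strongest peaks of each line with the nearest protein-coding gene, the 10 shared peaks with the highest mean rank percentile, the 5 strongest peaks of each line that were not shared, up to 4 members per gene list, and FOXO1, FOXO3, FOXO4 and FOXO6. Other genes named were chosen after their values were seen. Some items that the rule names are not reported here.

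The procedures were tested on simulated data. The overlap test of the THP-1 and U-937 lists called 1 of 40 runs with nothing planted and 40 of 40 runs with 15 shared sites planted. The simulated peaks were spread evenly over each chromosome, as in the test's own placements. These runs therefore do not cover lists that are clustered or concentrated at gene boundaries. The list test, run on 19866 genes with the number of U-937 target genes, called a list given 4 times the weight of other genes in 38 of 40 runs, and 4 of 720 tests of lists with nothing planted. Alternatives covered the significance threshold, the overlap rule, the boundary window, the number of strongest peaks, the placement, the measure of strength, and several subsets of peaks or genes chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.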

Results

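FOXO3A, a forkhead transcription factor that AKT phosphorylation keeps out of the nucleus, was mapped by CUT&Tag in THP-1 and U-937 cells. Both are established human lines with monocytic features, and the labels class both as acute myeloid leukemia cells. The aim given by the series' title was to map FOXO3A across the genome of leukemia cells. THP-1 had 3 libraries and U-937 had 2.

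Only 1 library of each line held peaks. THP-1 replicate 1 had 1282 peaks and U-937 replicate 1 had 2272, whereas THP-1 replicates 2 and 3 and U-937 replicate 2 had 0 each. Over the peaks on chromosomes, those of THP-1 had a median width of 475 bp against 238 bp in U-937, and covered 695 kb against 628 kb. The authors' median fold enrichment there was 6.57 in THP-1 (range 1.98 to 34.7) and 6.16 in U-937 (range 2.89 to 22.03). The median -log10 q was 13.3 in THP-1 and 4.79 in U-937. In THP-1, 245 peaks (19.1%) lay on 56 contigs outside the chromosomes and 1037 on chromosomes, 89 of these on chromosome Y. All U-937 peaks lay on chromosomes 1 to 22 and X, and neither list had a peak on the mitochondrial genome. Read depth was unknown, so peak numbers were not tested between lines, and no value below has a replicate check.

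The peaks of the lines lay in different parts of the genome. In U-937, 1202 of 2272 peaks (52.9%, 95% interval 50.8 to 55.0) had their summit within 1000 bp of a gene boundary, 10.4 times the 5.10% of random placements. In THP-1, 56 of 1037 peaks did (5.40%, 4.10 to 6.96), against 4.64% of random placements. Intergenic sequence held 72.3% of THP-1 peaks (random 48.4%) and 16.8% of U-937 peaks (random 43.4%). Gene bodies away from boundaries held 22.3% of THP-1 and 30.3% of U-937 peaks, below the random 47.0% and 51.5%.

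The difference in the boundary share was 47.5 percentage points, with an odds ratio of 19.7 (95% interval 14.8 to 26.6, Fisher's exact p = 2.33e-179, adjusted p = 5.43e-179). The U-937 share was above all random placements (permutation of positions, p = 0.001, the smallest possible), and the THP-1 share was not distinguishable from them (p = 0.13). The THP-1 share did pass this permutation test with a 500 bp window (3.38%, p = 0.032) and with protein-coding genes only (3.57%, p = 0.023). It also passed the permutation test without clustered peaks (7.67%, p = 0.001, the smallest possible) and without gene-free intervals, chromosome ends and mitochondrial pseudogenes (7.83%, p = 0.001, the smallest possible). In both of these last cases random peaks could still land in the stretches from which observed peaks were removed, which favoured a pass. Within 3000 bp the THP-1 share was 11.7%, below the 12.2% of random placements (permutation p = 0.33). The median distance from summit to the nearest protein-coding boundary was 189857 bp in THP-1 and 1262.5 bp in U-937, and 257 THP-1 but 2 U-937 peaks lay over 1 Mb away.

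**Figure D1:**
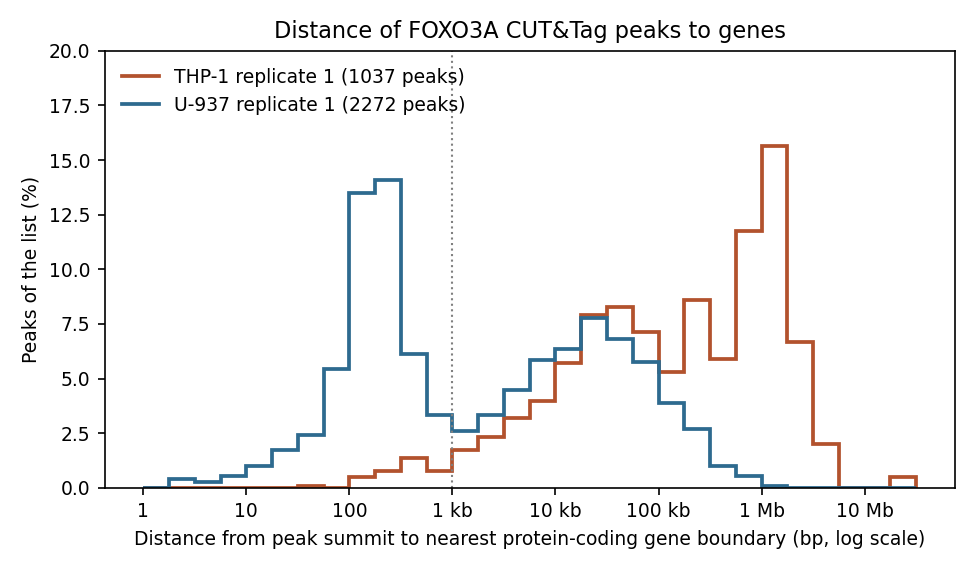
Share of each list's peaks (vertical axis, percent) by distance from the summit to the nearest protein-coding gene boundary (horizontal axis, bp, log scale), for THP-1 replicate 1 and U-937 replicate 1; the dotted line marks 1 kb. U-937 peaks pile up within 1 kb, whereas the THP-1 median lies at 189857 bp.

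THP-1 peaks concentrated in long gene-free stretches. The longest gene-free interval of each chromosome held 317 THP-1 peaks (30.6%, against 8.40% of random placements) and 0 U-937 peaks (upper limit 0.162%, random 3.93%). Chromosome ends reached 100000 bp inward from the first and the last gene or peak of a chromosome. All sequence before the first gene or peak counted too, whatever its length. These ends held 45 THP-1 peaks (4.34%, random 2.01%) and 6 U-937 peaks (0.264%, random 2.18%). The densest megabases of the THP-1 list were on chromosome Y at 10000001 to 11000000 with 56 peaks, chromosome 4 at 49000001 to 50000000 with 32, and chromosome 20 at 31000001 to 32000000 with 24. Another peak of the list lay within 10 kb of 37.1% of THP-1 and 4.31% of U-937 peaks. Each share set against random placements gave a permutation p of 0.001, the smallest possible. The random placements included assembly gaps, so a share below random does not by itself show avoidance.

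**Figure D2:**
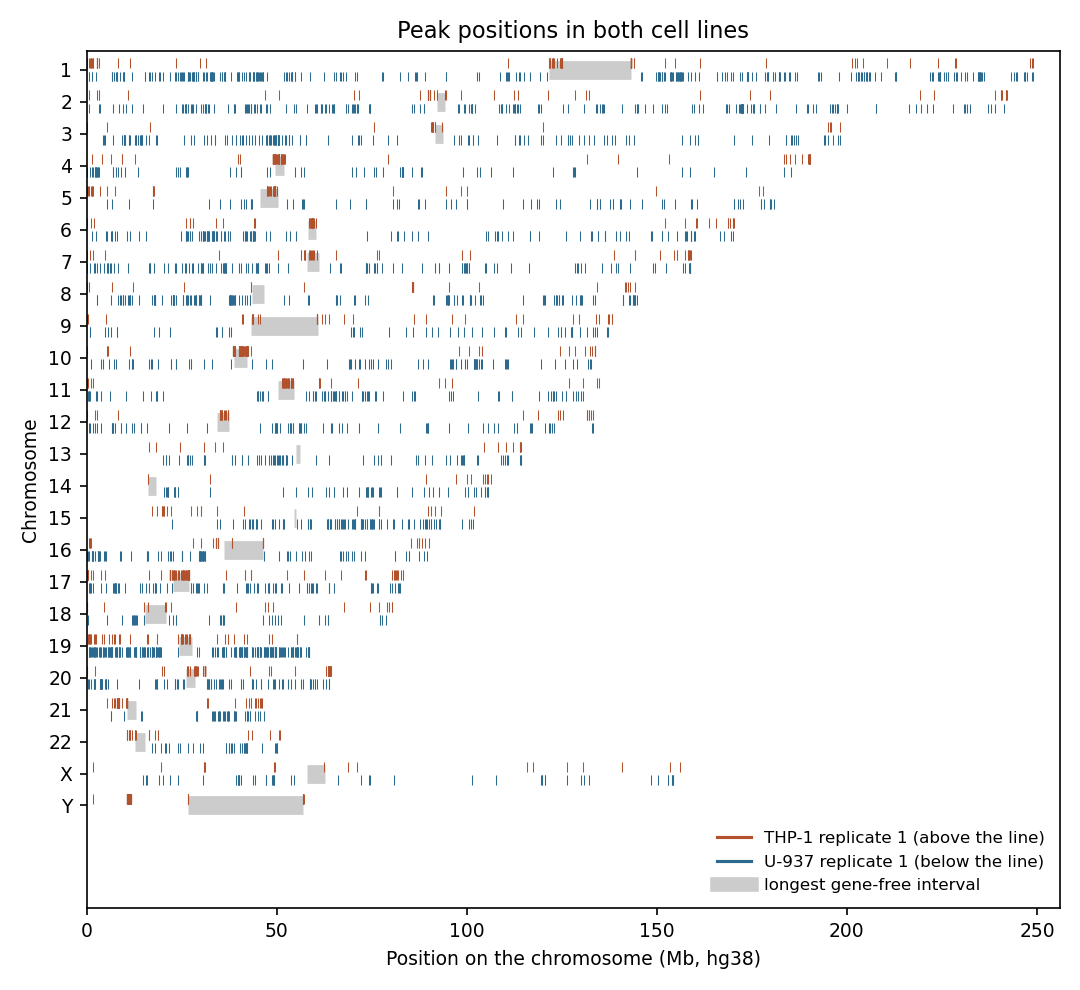
Position of each peak (ticks, Mb in hg38 on the horizontal axis) on each chromosome (vertical axis), with THP-1 replicate 1 above and U-937 replicate 1 below the line and the longest gene-free interval in grey. THP-1 peaks cluster in or beside many of the grey intervals, which hold 317 of them, and U-937 peaks are absent from them.

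The strongest THP-1 peak lay on chromosome 4 at 183399075 to 183399343, 45473 bp from CDKN2AIP, which encodes a protein that binds ARF, with a fold enrichment of 34.7. MTCO1P10 and MTCO1P24, nuclear copies of the mitochondrial gene MT-CO1, were among the sites of the 10 strongest THP-1 peaks, with folds of 33.8 and 31.8. A further peak of fold 33.7 lay in DDX11L2 on chromosome 2 at 113602929 to 113603486. Gene-poor sequence on chromosome 17 held peaks at 25920036 to 25920475 (fold 33.8) and 26603514 to 26604407 (fold 30.0), both nearest to WSB1, at 1373905 and 690201 bp. Others of the 10 were on chromosome 1 at 180116 to 181003 at 109201 bp from OR4F5 (fold 31.3), chromosome 4 at 50676782 to 50677387 at 1156824 bp from DCUN1D4 (fold 31.1) and within TUBB8B (fold 29.8).

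The 3 strongest U-937 peaks also lay at mitochondrial pseudogenes: MTATP8P2 within RGPD2 (fold 22.03, nearest gene PLGLB2), MTCO1P2 within AKAP6 (fold 20.4) and MTCO1P40, 716594 bp from KIF2B (fold 18.3). Gene boundaries carried 5 of the 10 strongest. These were ELL, a transcription elongation factor gene (fold 15.3), EEPD1 (fold 15.3), CACTIN (fold 14.5), the transcriptional repressor gene CIC (fold 14.4) and PNO1, a ribosome assembly factor gene (fold 13.8). The others were on chromosome 17 at 22521368 to 22521570 nearest to KCNJ18 at 816862 bp (fold 15.2) and at MTRNR2L12, nearest to EPHA6 at 196229 bp (fold 13.99). Among peaks that were not shared, the 5 strongest included those nearest to CDKN2AIP, MTCO1P10, WSB1 (fold 33.8) and MTCO1P24 in THP-1, and were MTCO1P40, EEPD1, CACTIN, MTRNR2L12 and PNO1 in U-937.

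The lines shared few peaks, and those shared were more than chance placed together. A U-937 peak overlapped 25 THP-1 peaks (2.41%), against a mean of 0.751 and a maximum of 5 in random placements (33.3 times, permutation p = 0.001, the smallest possible). Chromosome 19 held 11 of the 25 and chromosome 14 held 4. Of the 56 THP-1 peaks at gene boundaries 12 were shared (21.4%), against 13 of 981 elsewhere (1.33%), with an odds ratio of 20.3 (7.90 to 51.0, Fisher's exact p = 5.66e-10). U-937 peaks were 10.4 times as frequent as random at boundaries and absent from the gene-free intervals that held 317 THP-1 peaks. That alone raises this odds ratio, so it does not show preferential sharing at boundaries. Of the 1202 U-937 peaks at gene boundaries 12 were shared (0.998%), against 13 of 1070 elsewhere (1.21%), with an odds ratio of 0.82 (0.34 to 1.96, Fisher's exact p = 0.69). Placement that kept boundary peaks at boundaries gave a mean of 0.913.

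The 10 shared peaks with the highest mean rank percentile over both lists included those at or nearest to KCNJ18, PLGLB2, H2AC12, FSTL3, RASA3, DCAF12L1, DDX11L2, AKAP6 and HDGFL2. Those nearest KCNJ18, PLGLB2 and DCAF12L1 lay 816803, 65486 and 76275 bp from the gene, the PLGLB2 peak within RGPD2. The PLGLB2, DCAF12L1 and AKAP6 peaks overlapped mitochondrial pseudogenes. FSTL3, which encodes an activin-binding protein, carried the peak inside its span, with a fold of 7.16 in THP-1 and 11.5 in U-937. RASA3, a Ras GTPase-activating protein gene, had folds of 8.29 and 8.74. At -log10 q of at least 5, 11 peaks were shared.

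Genes with a boundary peak overlapped between lines. Of 19866 protein-coding genes, 44 had a boundary peak in THP-1 and 1395 in U-937, and 20 had one in both, against 3.09 for independent lists (odds ratio 11.2, 5.84 to 21.2, Fisher's exact p = 2.57e-12). At -log10 q of at least 5, 7 genes had one in both, against 1.18 (odds ratio 7.50, 2.71 to 18.1, Fisher's exact p = 0.00013). Among the 20 were ELL, CIC, HDGFL2, GSK3B, RAB8A, SIVA1, SF3A2, LMNB2 and 4 histone genes. Some rest on weak THP-1 peaks, with -log10 q of 3.58 at CIC, 4.70 at HDGFL2, 3.92 at RAB8A and 4.12 at SIVA1. Neighbouring genes can share a peak, and both peaks of a gene need not overlap. At GSK3B, which encodes a kinase that AKT inhibits, the U-937 peak was at 120094439 to 120095029 and the THP-1 peak at 120095082 to 120095377 on chromosome 3. The -log10 q of that THP-1 peak was 1.39, close to the lowest of its list.

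Shared peaks were stronger than the other peaks in U-937, and did not pass the test in THP-1. Their median fold enrichment in U-937 was 9.52 against 6.15 for the other 2247 peaks, a difference of 3.36 (permutation p = 1e-05, the smallest possible). In THP-1 it was 5.18 against 6.61, a difference of -1.43 (permutation p = 0.11). The difference between the lines in this contrast was not tested, as fold enrichment was used only within a list.

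Replication-dependent histone genes, which package newly made DNA, carried THP-1 boundary peaks more often than other genes. The 6 members of 56 were H2AC11, H2AC12, H2BC11, H2BC12, H3C12 and H4C4 (10.7%, 4.03 to 21.9), with an odds ratio of 62.4 (20.6 to 158, Fisher's exact p = 2.47e-09, adjusted p = 9.40e-08). The peaks at H2AC12 (fold 19.4) and H2BC11 (fold 16.97) each served a pair of genes, so that the members share peaks on chromosome 6 and are not independent. With the nearest boundary within 50000 bp the odds ratio was 4.99 (Fisher's exact adjusted p = 0.14). The 5 list members on other chromosomes were too few to show whether the excess extends beyond chromosome 6, and near-identical histone copies can share reads. The histone genes H2AC25 and H2BC26 on chromosome 1, named after their values were seen and not members of the list, shared a single THP-1 boundary peak (fold 7.70). GSK3B was the other THP-1 list member with a peak, 1 of 36 genes of PI3K-AKT-mTOR signalling (Fisher's exact adjusted p = 0.42). The other 17 lists had 0 members with a THP-1 peak, which for the 46 textbook FOXO targets allows a share of up to 7.71%.

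Ribosomal protein genes carried U-937 boundary peaks more often than other genes. A peak lay at 15 of 76 members (19.7%, 11.5 to 30.5), among them RPL7 (fold 8.34), RPL35 (fold 8.17) and RPS12 (fold 8.05). The odds ratio was 3.28 (1.73 to 5.86, Fisher's exact p = 0.000224, adjusted p = 0.00425). At -log10 q of at least 5 the odds ratio was 2.49 (Fisher's exact adjusted p = 0.32), and with the nearest boundary within 50000 bp it was 2.44 (adjusted p = 0.080). Histones had 10 of 56 members with a U-937 peak, H2AC11, H2AC12, H2BC11 and H2BC12 among them (odds ratio 2.89, Fisher's exact adjusted p = 0.065), and passed the test within 3000 bp (odds ratio 3.40, adjusted p = 0.0062). Here too members shared peaks, H2AC11 with H2BC11, H2AC12 with H2BC12 and H2AC20 with H2AC21, so they are not independent.

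Textbook FOXO targets did not carry U-937 boundary peaks more often than other genes. Of 46, TRIB1 (fold 5.95) and SESN3 (fold 4.48) had a peak, which gives an odds ratio of 0.60 (0.071 to 2.31, Fisher's exact adjusted p = 1). The direction changed with the window, with odds ratios of 0.33 within 500 bp, 1.06 within 3000 bp and 1.48 with the nearest boundary within 50000 bp. The SESN3 summit, at 1000 bp, lay at the limit of the window. Cell cycle genes had 8 of 46 members with a peak, among them CCND3 (fold 8.66), CDK2 (fold 8.37), PCNA (fold 7.17) and CDK4 (fold 6.93), with an odds ratio of 2.80 and an adjusted p of 0.13. DNA damage response genes had 6 of 37, among them ATM (fold 8.66), XRCC3 (fold 8.47) and XPC (fold 6.78), at an odds ratio of 2.57 and an adjusted p of 0.31. Glycolysis had 5 of 29, with PDK1 (fold 10.6), ENO1 (fold 6.84), GAPDH (fold 6.01) and GPI (fold 5.73), at an odds ratio of 2.76 and an adjusted p of 0.31.

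PI3K-AKT-mTOR signalling had 5 of 36 members with a U-937 peak, among them AKT2 (fold 9.25), GSK3B (fold 8.31), PPP2CA (fold 5.78) and PHLPP1 (fold 5.69), at an adjusted p of 0.50. The remaining lists had an adjusted p of 1 in U-937. Apoptosis had 4 of 40 members with a peak, HTRA2, CYCS, BCL2L1 and BAD. Autophagy and lysosome had 4 of 41, ATG3, BNIP3L, UVRAG and TFE3. Inflammation and NF-kB had 4 of 38, NFKBIB, RELB, NLRP3 and CCL3. Antioxidant defence had 3 of 31, TXN, NQO1 and SESN3. Recurrently mutated AML genes had 3 of 32, NPM1, SF3B1 and SMC3. Myeloid transcription factors had 3 of 36, JUN (fold 12.1), ZEB2 and LYL1. Monocyte and granulocyte genes had 1 of 39, CD68, and the MLL-fusion and HOXA programme had 1 of 27, ZEB2. The lists for T and B lymphocyte (25 genes), erythroid (19), hepatocyte (25) and neuronal genes (25) had 0 members with a peak in either line.

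**Figure D3:**
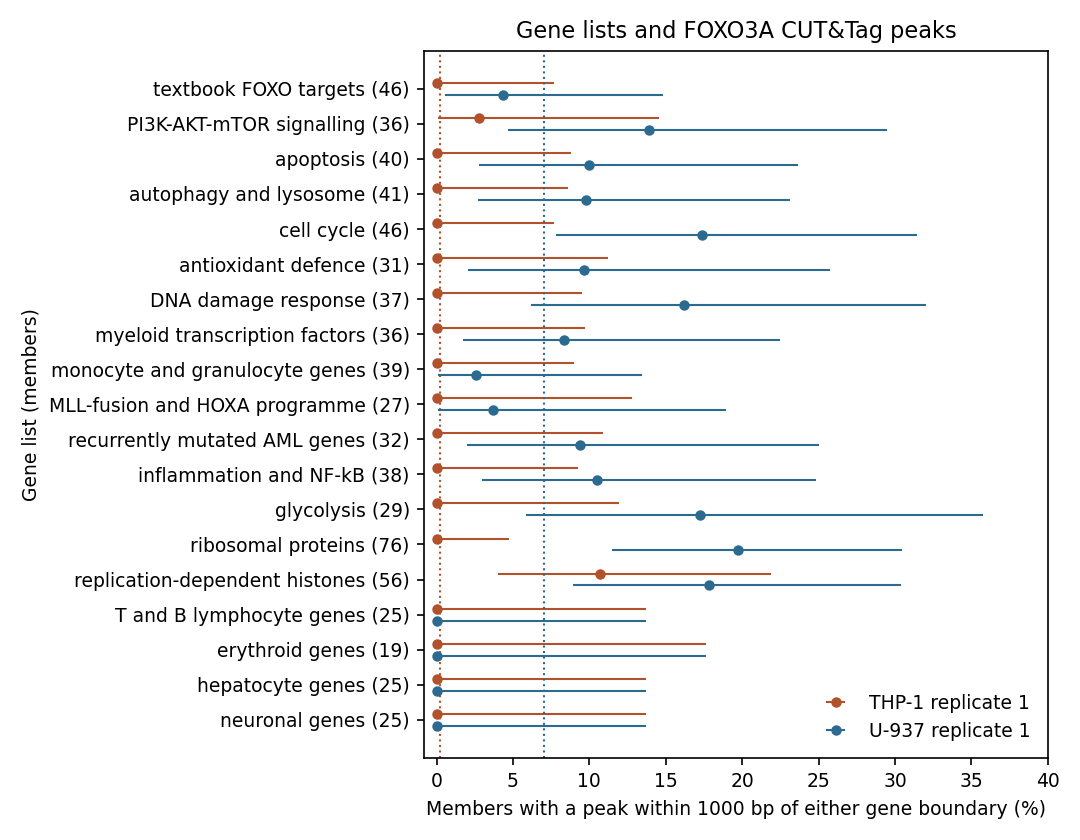
Share of each gene list's members (horizontal axis, percent; list and number of members on the vertical axis) with a peak within 1000 bp of either gene boundary, in THP-1 replicate 1 and U-937 replicate 1. Points are shares, lines are exact 95% intervals, and dotted lines mark the share of all protein-coding genes, 0.221% in THP-1 and 7.02% in U-937. The U-937 intervals for ribosomal proteins, histones and cell cycle genes and the THP-1 interval for histones lie above their dotted lines; of these, U-937 histones and cell cycle genes did not pass after adjustment.

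No gene list differed between lines after adjustment. Among genes with a boundary peak in 1 line only, histones made up 2 of 24 THP-1 genes and 6 of 1375 U-937 genes (odds ratio 20.7, 1.93 to 123, Fisher's exact p = 0.0074, adjusted p = 0.14). The histone difference passed within 3000 bp (odds ratio 11.8, Fisher's exact adjusted p = 0.021), although histone genes that share a peak are not independent. With 24 THP-1 genes, the other intervals were wide, with upper limits of 310 for textbook FOXO targets and 2234 for monocyte and granulocyte genes.

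No peak lay at FOXO1, FOXO3, FOXO4 or FOXO6. The nearest U-937 peaks were 104 kb from FOXO1, 299 kb from FOXO3, 1078 kb from FOXO4 and 86.6 kb from FOXO6. The nearest THP-1 peaks were 4597 kb from FOXO1, 43578 kb from FOXO3, 37.8 kb from FOXO4 and 9929 kb from FOXO6.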

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

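The tests of explanations in this part were chosen after the results were seen. The share of peaks at gene boundaries was 47.5 percentage points higher in U-937 than in THP-1 by a test of the difference itself, and 245 THP-1 peaks lay on contigs outside the chromosomes, which no comparison between lines used.

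Fewer THP-1 than U-937 peaks lay at gene boundaries. A looser threshold in the THP-1 list and peaks on chromosome Y were looked at by leaving peaks out. The difference was 56.2 points at -log10 q of at least 5 (THP-1 share 4.75%) and 47.0 points without chromosome Y (THP-1 share 5.91%). With 56 of 1037 THP-1 peaks at boundaries, neither removal could have brought the THP-1 share near that of U-937. These values therefore do not test either explanation. Reads of repeated sequence piling up at their assembled copies are a candidate source of part of the THP-1 list, as 360 peaks lay in gene-free intervals or at chromosome ends against at most 138 in random placements. Without these peaks and those at mitochondrial pseudogenes the THP-1 share was 7.83% (52 of 664 peaks) and the difference 45.4 points. With 56 boundary peaks in the whole THP-1 list, leaving out peaks elsewhere could not have closed the difference. Dense clusters outside these stretches, such as chromosome Y at 10000001 to 11000000, also stayed in. The values therefore do not show how much such reads contribute. A difference in FOXO3A binding between the lines stays open and untested, as does the different making of both lists, since each line has 1 library and line and list go together.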

How the results depend on the processing

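Several alternatives were chosen after seeing the data: without mitochondrial pseudogenes, chromosome Y, clustered peaks, or gene-free intervals, chromosome ends and mitochondrial pseudogenes together, with 1 threshold for both lists, with protein-coding genes only, and without chromosome 6 histones. Of the 167 alternative values not leaving out a library, 9 list odds ratios and 1 location share turned direction. The THP-1 boundary share within 3000 bp was 11.7%, below the random 12.2%. The U-937 odds ratio of textbook FOXO targets was 1.06 within 3000 bp and 1.48 with the nearest boundary within 50000 bp, where monocyte and granulocyte genes had 1.13 and the MLL-fusion and HOXA programme 1.23. Myeloid transcription factors had 0.88 within 500 bp, and antioxidant defence 0.81 at -log10 q of at least 5. THP-1 PI3K-AKT-mTOR signalling had 0 within 500 bp and at -log10 q of at least 5, and none of these passed the test in either setting. At -log10 q of at least 5, U-937 kept 1074 peaks, 11 peaks were shared and 0 U-937 gene lists passed. The THP-1 boundary share passed the placement test at 3.38% within 500 bp, 7.67% without clustered peaks, 7.83% without gene-free intervals, chromosome ends and mitochondrial pseudogenes, and 3.57% with protein-coding genes only. The 7.67% and the 7.83% were set against placements that still included the stretches from which peaks were left out. Within 3000 bp, 2 U-937 lists and 1 list between lines passed. With the nearest boundary within 50000 bp, 0 THP-1 and 0 U-937 lists passed. Without chromosome 6 the THP-1 histones had an odds ratio of 0 and 0 THP-1 lists passed, but the 5 genes left (interval 0 to 504) say nothing about stability. The cause was not tested, except that stricter thresholds and shorter lists leave fewer peaks or genes. Leaving out a library without peaks changes nothing by construction, and leaving out replicate 1 leaves its line without a set. No paired analysis was possible because only replicate 1 of each line held peaks. Not run were the motif alternatives and GC-matched backgrounds, which need a genome sequence, and the union over libraries, as each line had 1 list. Read depth was unknown, so it could not be weighed.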

Other observations

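The tests in this part were all chosen after the results, or values that bear on them, were seen. U-937 peaks overlapped or lay within 100 bp of genes annotated as tRNA in 13 cases, against a mean of 0.205 in random placements (permutation of positions, adjusted p = 0.005). For genes annotated as miRNA there were 8 cases, against 1.02 (permutation of positions, adjusted p = 0.005). These placements did not keep boundary peaks at boundaries, where U-937 peaks were 10.4 times as frequent as random. Whether either excess goes beyond that concentration was therefore not tested. THP-1 had 0 peaks at genes of either annotation, against random means of 0.088 and 0.603, so its 0 shows no contrast with U-937. Chromosome ends held 18 of the 50 strongest THP-1 peaks against 27 of the other 987 (odds ratio 20.0, Fisher's exact p = 5.24e-14), with a median fold of 19.0 at the ends and 6.53 elsewhere. In U-937 the ends held 0 of the 50 strongest peaks against 6 of the other 2222 (Fisher's exact p = 1), with median folds of 5.61 and 6.16.

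The 3 strongest U-937 peaks lay at mitochondrial pseudogenes, nuclear copies of mitochondrial genes, as did 4 of the 10 and 5 of the 50 strongest. Reads of the mitochondrial genome placed on its nuclear copies may be the source, and the THP-1 list, on which the pattern does not rest, had 13 such peaks against at most 2 in random placements. In THP-1, MT-CO1 copies took 8 of 13 peaks (61.5%) and 13.9% of the bases of such pseudogenes (exact binomial p = 9.24e-05). In U-937, MT-CO1 copies took 2 of 13 peaks, a difference with a Fisher's exact p of 0.041. These tests cannot decide whether the mitochondrial genome was evenly covered. They take reads to fall on copies in proportion to bases, and the likeness of each copy to that genome was not examined. MT-CO1 was also picked after its peaks were seen, and no biological explanation was tested.

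U-937 peaks lay at gene boundaries. Whether collapsed repeats contribute to the peaks at boundaries could not be tested, since the 6 U-937 peaks in gene-free intervals or at chromosome ends concern sequence that is mostly away from boundaries. Tagging of open promoters without regard to FOXO3A is a candidate explanation, since ribosomal protein genes, used in every cell, had an odds ratio of 3.28 and textbook FOXO targets 0.60. These 2 lists were not tested against each other. Monocyte and granulocyte genes had an odds ratio of 0.35 and myeloid transcription factors 1.20, and neither list passed. The ribosomal odds ratio stayed above that of FOXO targets, at 3.73 against 0.33 within 500 bp and 2.49 against 0 at -log10 q of at least 5. It was 3.00 against 1.06 within 3000 bp and 2.44 against 1.48 with the nearest boundary within 50000 bp. The direction for FOXO targets thus changed with the setting. The ribosomal call was lost at -log10 q of at least 5 and with the nearest boundary within 50000 bp. FOXO3A binding at these genes stays open, as neither a control library nor motifs were analysed here.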
